A study of Mus musculus with 6 samples.

How the data were processed

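Mature microRNAs (miRNAs) were measured by real-time PCR in osteoclasts of mouse bone marrow. The cells carried the osteoclast receptors OSCAR and CTR and were taken from marrow by magnetic sorting 2 weeks after transection of the anterior cruciate ligament (ACLT) or a Sham operation, per the labels. There were 3 ACLT samples and 3 Sham samples, numbered 1 to 3 in each group by the labels. The series text states that equal amounts of RNA from 3 mice per group were pooled. Whether each sample is a mouse or a repeat measurement of a pool is not given in the sources used here, so the p-values measure only the spread between these samples, which may be technical.

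Per the labels' protocols, RNA was extracted with Trizol, reverse transcribed with a QuantiMir kit and amplified with SYBR Green dye on a ViiA7 instrument over 40 cycles. The assays lay on 2 plates of 384 wells. The first deposited table holds the raw threshold cycle (Ct) of each well, on which a lower value is more RNA. The second deposited table holds ΔCt, a log2 scale; the values equal the raw Ct minus the Ct of a single reference well of the same sample and plate, named U6 per the file headers. The third holds the authors' deposited fold change, a linear ratio of ACLT to Sham, which was recomputed from ΔCt as 2 to the power of minus ΔΔCt with a largest deviation of 3.6e-15. Threshold and baseline settings are not given in the sources used here.

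The raw table lists 719 wells, of which 110 had a Ct in all 6 samples and 609 had none. No well had a Ct in only some of the samples. The 110 wells held 104 miRNA assays and 6 reference wells, which are 3 reference assays on each of 2 plates. A pair of wells was listed 2 times, once with values and once without, and the line with values was used. ΔCt was given for 103 of the 104 miRNAs. 2 lines of the ΔCt table were not analysed here. A qPCR array has no read depth; precision was limited by the number of samples.

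Levels were taken as minus ΔCt, so that higher is more RNA and 1 unit is a factor of 2 at full amplification efficiency, and are given as mean ± SD over the 3 samples of a group. A miRNA was tested if its raw Ct was under 35 in all 3 samples of at least 1 group, which left 100 miRNAs. ACLT and Sham were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. In this fit limma pooled the spread over all miRNAs, with 400 degrees of freedom in total, which treats wells of a sample as independent although they share cells, cDNA and normalizer. The small p-values therefore rest on far fewer independent units than the degrees of freedom state. On simulated data with 100 miRNAs and the same design, the fit called 11.1% of miRNAs changed by 1 on the log2 scale, 59.7% of those changed by 2, 95.5% of those changed by 3 and 1.5% of unchanged miRNAs. The simulated values were independent between wells and between samples. They held neither a normalizer shared by wells nor the tie between samples described below, so these rates may not hold for the real data.

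Lists of miRNAs were fixed before the data were examined: miRNAs described as favouring or restraining osteoclasts, miRNA families and gene clusters, and miRNAs of other cell types that a marrow sort could hold. Lists with at least 3 tested members were compared with the other miRNAs by limma's camera with a preset correlation of 0.01 and again with an estimated correlation; fry tested each list on its own. The miRNAs named are the 12 largest passing changes in each direction whose groups did not overlap, or, where fewer passed, all of these and the next by p up to 10; the 3 members of each list with the smallest p; all tested members of smaller lists; the reference RNAs; and the 5 miRNAs with the lowest Ct. Any other name was chosen after its values were seen. Raw Ct of the reference wells and the number of detected miRNAs were compared by exact two-sided permutation tests, whose smallest p with 3 against 3 is 0.1.

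Before any test, the samples of a group were compared with each other. For each of the 15 pairs of samples the raw Ct values were scanned for a factor such that the value of a well in one sample equals that in the other times the factor, or divided by it, within 0.002 cycles. The scan was checked on simulated wells, where it found 70 of 70 wells built with a factor and at most 4 in pairs of independent samples. Its result is given with the data, and it led to 3 alternatives chosen after seeing the data: the second and the third sample of each group averaged into 1, only the first and the second sample of each group, and only miRNAs off the factor in both groups. The alternatives fixed beforehand were other normalizations, other Ct limits, other variance models, the replicate number as a block and leaving out each sample. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Names of miRNA genes and their neighbours came from a RefSeq gene table of the assembly GRCm38.p6, in which all 100 tested miRNAs had a match.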

Results

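The data are Ct values of 104 miRNAs detected in sorted mouse osteoclasts, the multinucleated cells that resorb bone, 2 weeks after ACLT or Sham surgery. ACLT destabilises the knee and is a common model of osteoarthritis. The median Ct per sample lay between 27.8 and 28.4, and single values between 19.7 and 37.3. In the ACLT samples 101, 98 and 100 miRNAs had a Ct under 35, and in the Sham samples 102, 102 and 101, a mean difference of -2 (exact permutation p = 0.2, two-sided). The lowest mean Ct belonged to miR-21, let-7a, let-7c, miR-338-5p and let-7i.

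In most wells the second and the third sample of a group were tied to each other. In the ACLT group, the Ct of the third sample equalled that of the second multiplied by 0.99 in 48 wells and divided by it in 29, which makes 77 of 110 wells within 0.002 cycles. In the Sham group, the factor was 0.97843 or its reciprocal 1.02204, in 82 of 110 wells. The other 13 pairs of samples, compared well by well, shared such a factor in 2 to 4 wells. Values of different wells were not compared. Of the 104 miRNAs, 71 were on the factor in both groups, 6 in the ACLT group alone, 11 in the Sham group alone and 16 in neither. None of the 6 reference wells was on the factor in either group. For a miRNA on the factor, the SD over 3 samples counts a dependent value as a separate sample. Whether its second value was itself taken from another well was not tested, so the fold change may be affected too. Because limma pooled the spread over all miRNAs, the dependent wells enter the p-values of every tested miRNA, those off the factor included.

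**Figure D1:**
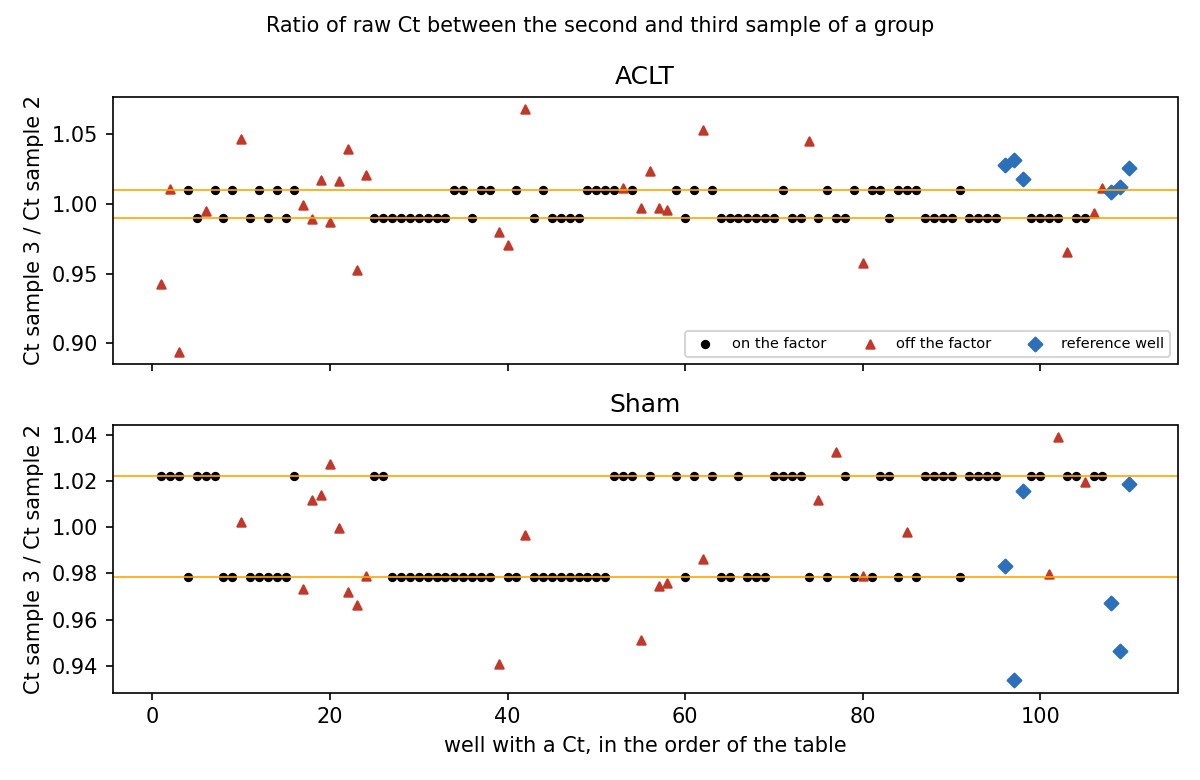
Raw Ct of the third sample divided by raw Ct of the second sample (y axis, no unit) for each of the 110 wells with a Ct (x axis, order of the table), in the ACLT group above and the Sham group below. Black points lie within 0.002 cycles of the factor or its reciprocal (orange lines; 77 wells in the ACLT group, 82 in the Sham group), red triangles are miRNA wells off the factor and blue diamonds are reference wells, all of which are off it.

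The comparison of ACLT with Sham asks which miRNAs of osteoclasts differ after the knee is destabilised. miR-21, which represses Pdcd4 and promotes osteoclast formation, was 22.1-fold higher in ACLT, with a level of 5.90 ± 0.30 against 1.43 ± 0.31 (SD, n = 3 each; log2 scale relative to U6). miR-214 was 10.8-fold higher (4.47 ± 0.48 against 1.03 ± 0.05), and miR-148a was 9.24-fold higher (3.73 ± 0.50 against 0.53 ± 0.48). 4 of the 5 members of the miR-30 family, 3 of them by more than 2 log2 units, were higher as well. A smaller group, led by miR-99b*, which lay near the Ct limit in ACLT, and miR-185, was lower in ACLT. With the second and the third sample of each group averaged no lower miRNA passed.

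Of the 100 miRNAs tested with limma, 20 passed an adjusted p of 0.05, 13 higher and 7 lower in ACLT. With the second and the third sample of each group averaged into 1 in all wells, on the factor or not, a setting chosen after seeing the data, 11 passed, all 11 higher, and miR-30c and miR-378 were lost, miR-378 with a change of 2.06 against 2.09 (adjusted p = 0.063; 18 of either direction had an unadjusted limma p under 0.05). All 13 higher miRNAs were among the 16 that were off the factor in both groups, whereas 6 of the 7 lower miRNAs were on it in both and miR-99b* was on it in the Sham group. The 3 ACLT values did not overlap the 3 Sham values for any of the 20, and for 26 of all 100. Chance gives 10% if all samples are independent. For the 70 tested miRNAs on the factor in both groups they are not, and chance is higher there, so 26 cannot be weighed against 10%. The split depended on the scaling: 13 higher and 23 lower when centred on the median miRNA, 11 and 14 after quantile normalization, 6 and 34 with the mean of the 3 reference assays, 1 and 87 with reference 3 alone, and 0 and 0 with reference 2 alone. With reference 2 miR-21 kept much of its size (3.82), and miR-185 fell by more (-2.66, against -2.02 with U6). Neither passed (limma adjusted p = 0.817 and 0.986). With reference 3, in contrast, miR-214 stood at 0.70 and miR-145 at -0.13. The change of miR-21 was 2.47 after quantile normalization, 3.34 with the mean of the 3 references and 1.73 with reference 3.

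After the 3 named above, the largest rises were those of miR-30d (2.93 ± 0.62, SE of the log2 change), miR-30a (2.61 ± 0.61), miR-145 (2.61 ± 0.60), miR-200c (2.49 ± 0.60) and miR-199a-3p (2.43 ± 0.61). miR-29a, miR-30e, miR-200b and miR-378 rose by 2.25, 2.24, 2.24 and 2.09. The thirteenth, miR-30c, at 1.74, was named after its value was seen. Adjusted p-values from limma ran from 4.73e-13 for miR-21 and 3.78e-07 for miR-214 to 0.00571 for miR-378 and 0.0334 for miR-30c. With the second and the third sample averaged, the change of miR-21 was 4.60 (adjusted p = 1.46e-12) and that of miR-214 was 3.31 (adjusted p = 5.31e-05). With only the first and the second sample of each group, miR-21, miR-214 and miR-148a alone passed, while miR-30e (2.50) and miR-200b (2.27) kept their size without passing. The mean Sham Ct of miR-21, miR-214 and miR-30a lay within 0.0004 cycles of a multiple of 0.1. The mean Ct of the 13 in ACLT lay between 20.4 and 23.9.

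The 7 lower miRNAs were miR-99b* (log2 change -2.14 ± 0.81, SE), miR-185 (-2.02 ± 0.59), miR-192 (-1.72 ± 0.59), miR-186 (-1.71 ± 0.59), miR-205 (-1.63 ± 0.59), miR-222 (-1.63 ± 0.59) and miR-203 (-1.56 ± 0.60). Their adjusted p-values from limma lay between 0.00571 for miR-185 and 0.0465 for miR-203. With the replicate number as a block, which leaves the size of a change as it is, only miR-185 of the 7 still passed. With the second and the third sample averaged, the change of miR-185 was -1.78 (adjusted p = 0.139) and that of miR-99b* was -2.18 (adjusted p = 0.108), so these kept most or all of their size; for miR-99b* this merged ACLT values that were not tied to each other. After quantile normalization miR-99b* stood at -0.55 (adjusted p = 0.293). The mean Ct of the 7 in ACLT was between 30.4 and 35.2, the highest being that of miR-99b*. This miRNA was tested through its Sham values alone, since its Ct in ACLT sample 2 was 36.2, over the limit of 35. The number of lower miRNAs was 1, 0 and 3 without ACLT sample 1, 2 and 3, and 16, 1 and 1 without Sham sample 1, 2 and 3. The next 3 by p did not pass: miR-320 at -1.38, miR-676* at -1.84 and miR-181a at -1.32, with adjusted p-values of 0.0963, 0.112 and 0.112.

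**Figure D2:**
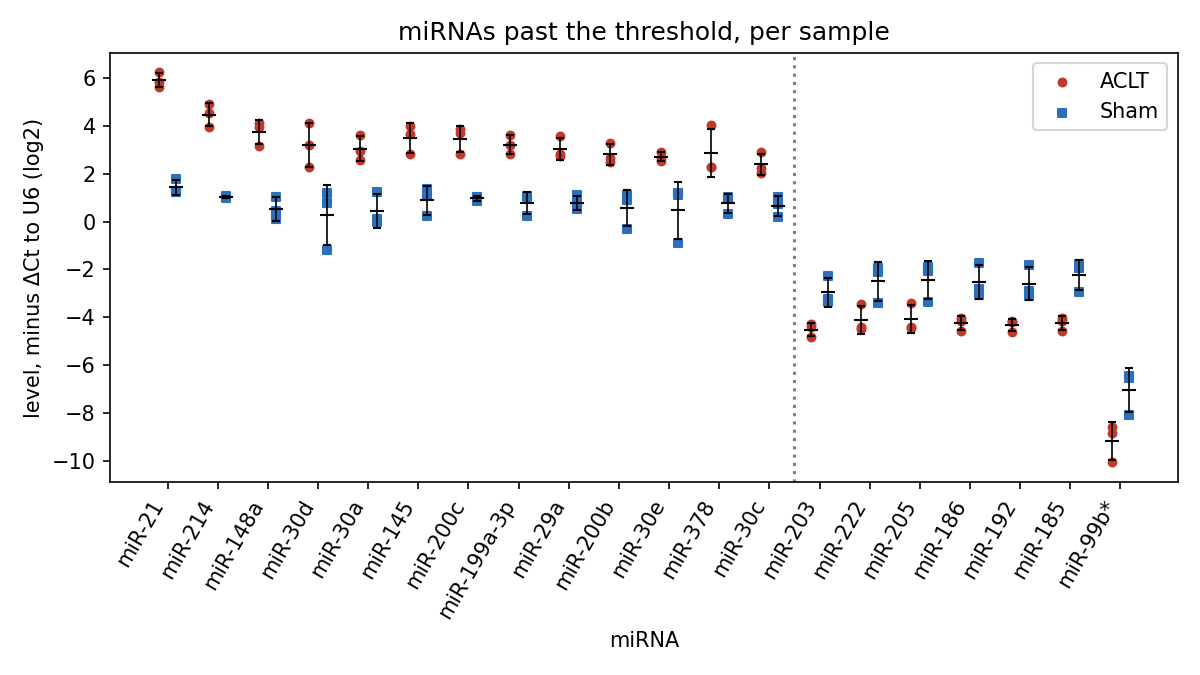
Level of the 20 miRNAs past the threshold (y axis, minus ΔCt relative to U6, log2) in each ACLT sample (red circles) and each Sham sample (blue squares), with the group mean and SD in black; the dotted line parts the 13 higher from the 7 lower miRNAs. miR-21 lies at 5.90 in ACLT and 1.43 in Sham on average, and the third sample of 6 of the 7 lower miRNAs is a fixed multiple of the second in both groups on the Ct scale.

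The fitted changes and the ratios in the authors' deposited table come from the same ΔCt means, so their directions are equal by construction. Of the ratios of the 100 tested miRNAs in the authors' deposited table, 24 were above 2 and 10 were below 0.5.

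Among miRNAs described as favouring osteoclasts, 8 were tested and 5 rose, 6 when adjusted over the list alone; none fell. miR-21, miR-214, miR-148a, miR-199a-3p and miR-29a passed, while miR-29b (1.41), miR-29c (0.90) and miR-183 (1.11), named after their values were seen, did not pass over all miRNAs. The list stood above the other miRNAs (limma camera, adjusted p = 4.48e-06), with an adjusted p = 0.059 with an estimated correlation, so that this call was lost there. 7 of its 8 members were off the factor in both groups. In the miR-30 family, whose members share a seed, 4 of 5 rose, 5 when adjusted over the list alone, and miR-30b stood at 1.25 (adjusted p = 0.161). The camera test gave an adjusted p = 0.00382, and an adjusted p = 0.424 with an estimated correlation, which ended the call. All 5 were off the factor. miR-30a (UGUAAACAUCCUCGACUGGAAG) differs by 1 base from miR-30d (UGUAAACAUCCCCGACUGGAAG) and from miR-30e (UGUAAACAUCCUUGACUGGAAG), so the assays of these 3 can share signal. With reference 3 as the normalizer, miR-30a and miR-30e stood at -0.13 and -0.50.

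Among the mesenchymal miRNAs, which cells of the stroma and vessel wall carry, 3 of 5 rose, also when adjusted over the list alone. These were miR-214, miR-145 and miR-199a-3p; the first and the last are also on the osteoclast-favouring list. miR-143, which shares a transcript with miR-145, stood at -0.67 ± 0.59 and miR-152 at -0.76 ± 0.59, and the list as a set did not pass (adjusted p = 0.167 by limma camera). The epithelial list moved apart: miR-200c and miR-200b rose and miR-205 and miR-203 fell, 4 of 5 members, 2 in each direction, also over the list alone (camera adjusted p = 0.802). Of the erythroid miRNAs 0 of 3 passed; miR-451 stood at 1.21, miR-486 at -0.62 and miR-144 at -0.54 (camera adjusted p = 0.802). Of the lymphoid miRNAs 0 of 3 passed, with miR-181a at -1.32, miR-150 at 1.08 and miR-181d at -0.40 (camera adjusted p = 0.802). All 3 erythroid and all 3 lymphoid miRNAs were on the factor in both groups. Their lack of a call therefore does not show that such cells were absent or unchanged. The endothelial miR-126-3p (0.29 ± 0.64), the muscle miR-206 (-0.22 ± 0.63) and the neural miR-128 (-0.97 ± 0.59) and miR-7a (0.19 ± 0.59) did not pass. Each of these was also on the factor in both groups.

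The other lists did not pass against the remaining miRNAs by camera, and only miR-21 passed among their members. Of the miRNAs described as restraining osteoclasts 0 of 6 passed, with miR-146a at 1.04, miR-340-5p at -0.94 and miR-503 at 0.70 (camera adjusted p = 0.802). In the myeloid list miR-21 alone of 6 rose, with miR-146a at 1.04 and miR-22* at -0.80 (adjusted p = 0.646). In the list of NF-kB and inflammation miR-21 alone of 3 rose, with miR-146a at 1.04 and miR-146b at -0.40 (camera adjusted p = 0.167). Tested on its own by limma's fry, which asks whether the members move one way, this list passed (adjusted p = 0.0133), as did the osteoclast-favouring list (adjusted p = 0.000291); the miR-30 family (adjusted p = 0.051) and the other lists did not. The same counts held when adjusted over each of these lists alone. The let-7 family had 0 of 9 past the threshold, with let-7a at 1.18, let-7e at 1.14 and miR-98 at 0.84 (adjusted p = 0.802). The paralogous clusters of miR-17 and miR-106b had 0 of 4, with miR-93 at 0.77, miR-106b at 0.60 and miR-92a at 0.77 (adjusted p = 0.802). The imprinted Dlk1-Dio3 cluster had 0 of 6, with miR-134 at -0.73, miR-382 at -0.69 and miR-370 at 0.53 (adjusted p = 0.735). On the factor in both groups were 5 of 9 let-7 miRNAs, 4 of 4 of the paralogous clusters and 6 of 6 of the Dlk1-Dio3 cluster. So were 3 of 6 restraining, 3 of 6 myeloid and 1 of 3 inflammation miRNAs. miR-297a of the Sfmbt2 cluster stood at 0.99 and miR-503 was also the tested member of the family of miR-15 and miR-16; no member of the X-linked germline cluster was tested. Of the miRNAs with the lowest Ct, let-7c stood at 0.48, miR-338-5p at -0.36 and let-7i at 0.10. A change of 1 on the log2 scale was called in 11.1% of simulated cases. Even with the independent wells and samples of the simulation, values of this size were thus mostly not told from 0. Leaving out 1 sample moved 27 of the 30 named miRNAs that did not pass by over 1.5 times relative to the change with all samples. It did so for 0 of the 19 named miRNAs that passed. Such a ratio favours large changes, so these counts do not compare stability. The range was 0.055 to 1.13 for miR-106b (without ACLT sample 1 and 2) and 0.43 to 1.53 for miR-146a (without ACLT sample 3 and 1). For miR-503 it was 0.14 to 1.25 (without Sham sample 1 and 2). Among those that passed, miR-30d ranged from 2.21 to 3.39 (without Sham sample 1 and ACLT sample 2). miR-30e ranged from 1.55 to 2.61 (without Sham sample 1 and 3).

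The reference wells address how far the normalization holds. Reference 1, the U6 normalizer, had a Ct of 26.3 ± 0.49 in ACLT and 26.2 ± 0.80 in Sham on plate 1 (SD, n = 3 each; exact permutation p = 1), and a difference of -0.16 cycles on plate 2 (exact permutation p = 0.8). Reference 2, an unnamed assay, differed by -0.57 and -0.29 cycles on the 2 plates, with exact permutation p-values of 0.8 and 0.6. Reference 3, also unnamed, had a Ct of 28.3 ± 0.79 in ACLT and 31.0 ± 0.53 in Sham on plate 1 and of 28.3 ± 0.56 and 31.1 ± 0.29 on plate 2. The differences of -2.66 and -2.87 cycles, with no overlap between groups, had an exact permutation p = 0.1, the smallest that 3 against 3 can give. With reference 3 as the normalizer only miR-21 of the 13 higher miRNAs still passed as higher.

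**Figure D3:**
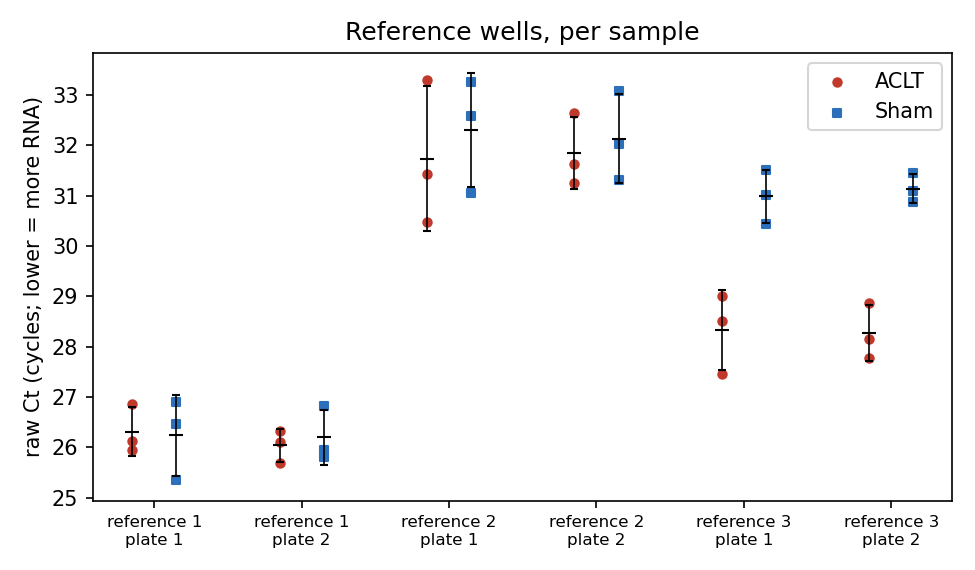
Raw Ct (y axis, cycles; lower is more RNA) of the 3 reference assays on each of the 2 plates in each ACLT sample (red circles) and Sham sample (blue squares), with the group mean and SD in black. Reference 1 and reference 2 overlap between the groups, and reference 3 lies at 28.3 in ACLT and at 31.0 and 31.1 in Sham.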

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

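miR-200a had a raw Ct in all 6 samples, with a mean of 23.7 cycles, but no value in the deposited ΔCt table or ratio table, so it was left out of the fit and of the lists, though its Ct counts among the 104 detected miRNAs. Its Ct was 23.8 ± 0.89 in ACLT and 23.6 ± 0.56 in Sham (SD, n = 3 each). In Sham this miRNA was on the factor, so the Sham SD and the permutation test count a dependent value. Relative to the U6 well of its plate the log2 difference was -0.12 (exact permutation p = 0.5, two-sided; smallest possible 0.1). Groups of 3 samples were not searched for samples far from the others.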

How the results depend on the processing

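The alternatives that average the second and the third sample or leave the third out of both groups, and the restriction to miRNAs off the factor, were chosen after seeing the data. Averaging or leaving out the third takes the second value of a well on the factor as measured, which was not tested. The count of 20 miRNAs was 36 when centred on the median miRNA, 0 with reference 2 alone (2 at an unadjusted p under 0.05 in limma), 88 with reference 3 alone, 40 with the mean of the 3 references, 11 with samples 2 and 3 averaged, 3 with only samples 1 and 2, and 13 to 30 when leaving out each sample. The 13 higher miRNAs became 0 with reference 2, 1 with reference 3, 6 with the mean of the references and 3 with only samples 1 and 2, and 11 to 14 when leaving out each sample. With reference 2 (miR-21 3.82, miR-148a 2.57) and with only samples 1 and 2 (miR-30e 2.50, miR-200b 2.27) these changes kept much or all of their size and lost the adjusted p, while with reference 3 they shrank or reversed. The 7 lower miRNAs became 23 when centred on the median miRNA, 14 after quantile normalization, 12 on raw Ct, 0, 87 and 34 with reference 2, reference 3 and the mean of the references, 0 in each of the 3 settings chosen after seeing the data (by construction for miRNAs off the factor, which hold no lower call) and 0 to 16 when leaving out each sample. miRNAs off the factor in both groups, tested alone, gave 15 of 16, all higher. Quantile normalization kept 6 of the 13 higher miRNAs and left miR-200b at 0.36 and miR-30e at 0.46. The other filters, variance models and raw Ct kept all 13 higher. Among the lower miRNAs, no filter on Ct lost miR-203. A Ct under 32, or under 35 in all 6 samples, left miR-99b* untested. The number of detected miRNAs, -2 for ACLT against Sham, was 0 with Ct under 38, where all 104 were detected in each sample, and -1.17 to -2.67 when leaving out each sample. The 2 called lists became 1 after quantile normalization, 4 with reference 3 and 0 with an estimated correlation. The mean difference of reference 1 went from -0.041 to 0.337 cycles relative to the median miRNA, and that of reference 2 from -0.426 to -0.048. The median change of all miRNAs was 0.24, and moved to -0.17 when centred on the median miRNA, to -0.33, -2.50 and -0.87 with reference 2, reference 3 and the mean of the references and to -0.10 after quantile normalization. It was 0.49 with samples 2 and 3 averaged and 0.11 with only samples 1 and 2, and leaving out each sample gave -0.0078 (without Sham sample 1) to 0.51 (without Sham sample 2), with 0.39 without ACLT sample 2 and 0.098 without ACLT sample 3. Normalizers shift all miRNAs of a plate by the same amount, which shows the cause of the reversals they bring; the cause of the others was not tested.

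The replicate numbers gave no clear pairing of the samples. Same-numbered samples had correlations of deviations of 0.245, 0.056 and 0.066, for samples 1, 2 and 3. The first of these was the highest of any ACLT and Sham pair. Sample 3 of ACLT correlated best with sample 2 of Sham (0.22). Since samples 2 and 3 of a group are tied in most wells, these correlations cannot show whether samples were paired. With the replicate number as a block, 14 miRNAs passed, 13 higher and 1 lower.

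With reference 3 alone, miR-30a was -0.13, miR-145 -0.13, miR-200c -0.24, miR-199a-3p -0.30, miR-29a -0.49, miR-30e -0.50, miR-200b -0.50, miR-378 -0.64, miR-146a -1.69, miR-503 -2.03, miR-93 -1.96, miR-92a -1.97, miR-106b -2.13, let-7a -1.56, let-7e -1.59, miR-98 -1.90, miR-370 -2.21, miR-297a -1.75, miR-451 -1.52, miR-150 -1.65, miR-126-3p -2.44, miR-7a -2.55, let-7c -2.26 and let-7i -2.63. With the mean of the 3 references, miR-146a was -0.081, miR-503 -0.42, miR-93 -0.35, miR-92a -0.36, miR-106b -0.52, miR-98 -0.29, miR-370 -0.60, miR-297a -0.14, miR-150 -0.044, miR-126-3p -0.83, miR-7a -0.94, let-7c -0.65 and let-7i -1.03. With reference 2 alone, miR-106b was -0.039, miR-370 -0.12, miR-126-3p -0.35, miR-7a -0.45, let-7c -0.17 and let-7i -0.54. After quantile normalization, miR-146a was -0.27, miR-22* 0.73, miR-106b -0.077, let-7a -0.39, miR-98 -0.17, miR-150 -0.14, miR-126-3p -0.18, let-7c -0.90 and let-7i -1.01. Centred on the median miRNA, miR-126-3p was -0.16, miR-7a -0.27 and let-7i -0.35. With only samples 1 and 2, let-7c was -0.49, miR-338-5p 0.017 and let-7i -0.016. When leaving out each sample, miR-206 ranged from -0.48 to 0.17, miR-7a from -0.26 to 0.46, let-7c from -0.43 to 1.21 and let-7i from -0.49 to 0.47. Leaving an undetermined Ct missing was not run, since no tested miRNA had one, and neither was a pseudocount, since the values are on a log scale. With no blank wells used here, how far the signal lies above background is unknown; miRNAs with a Ct near 35 are the least certain.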

Other observations

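The tests of the factor between samples and of the order of wells, and the test of mesenchymal cells, were chosen only after the result was seen; the tests of the normalizer, of assays 1 base apart, of other splits and of neighbouring genes were set beforehand.

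Biology beyond the lists was limited to pairs of miRNAs whose genes lie within 10000 bases of each other in the assembly GRCm38.p6. The hypothesis was that such neighbours change together. Over 28 pairs the median absolute difference in log2 change was 0.764, against 1.14 for shuffled values (permutation p = 0.053), so the threshold was missed. Neighbours that stood far apart were miR-145 and miR-143 (2.61 and -0.67) and miR-99b* and let-7e (-2.14 and 1.14). miR-143 and let-7e were on the factor in both groups and miR-99b* in the Sham group. Since 70 of the 100 tested miRNAs were on it in both groups, this limits the test of neighbours as well. miR-214 and miR-199a-3p both rose (3.44 and 2.43), as did miR-30e and miR-30c (2.24 and 1.74).

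In both groups the Ct of the third sample was a fixed multiple of that of the second in most wells, at least 77 of 110. The same cDNA or pool measured again would carry the factor into the reference wells, and 0 of 12 reference ratios lay on it. A changed threshold or baseline moves the wells of a plate one way, but the smaller direction held at least 40.8% of the linked miRNA wells of plate 1. A candidate explanation is that these values were derived by calculation, for a reason that the data do not show. The third could come from the second, or both from a common source. At most 4 wells were linked in any other pair of samples. That scan compared only values of the same well, so a source in another well, the first sample included, was not looked for and stays open. No biological explanation was tested, and the 16 miRNAs off the factor in both groups hold all 13 higher calls (Fisher's exact p = 7.9e-14) and 3 others, all with a positive change. That p counts miRNAs as independent units, although they come from the same samples and include the miR-29 and miR-30 families in adjoining wells, so it overstates the evidence.

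The mean Sham Ct lay within 0.0004 cycles of a multiple of 0.1 for 3 of the 16 miRNAs off the factor in both groups (miR-21 at 24.8, miR-214 at 25.2 and miR-30a at 25.8) and for 2 of the other 88. For values with 3 decimals chance gives 1%, and in ACLT the counts were 0 of 16 and 0 of 88. This was noticed after the values were seen and was not tested.

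Along the order of wells, Ct rose in long runs. In the first sample of each group the longest rising subsequence over 104 miRNAs was 49 (ACLT) and 41 (Sham), above the highest of 10000 permutations within blocks of 10 wells (39 and 36; permutation p = 1e-04, the smallest they can give). In the other 4 samples it was 31, 30, 29 and 32 (ACLT samples 2 and 3, Sham samples 2 and 3), not above the highest permutation but above the median of 25, with permutation p-values of 0.0008, 0.01, 0.03 and 0.0002. A candidate explanation for the first samples is that values were ordered by well, and for the other 4 this stays open. A position effect on the plate stays open too: the wells of a reference assay on the 2 plates differed by at most 0.157 cycles on average, but they lie at similar positions.

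For the 13 higher miRNAs, centring on the median miRNA in place of the normalizer kept 13 of 13 higher. This argues against a shift of the normalizer, shared by all miRNAs, as the whole cause of the higher calls. A rise relative to other miRNAs of the plate cannot come from the normalizer in any case, so the test says nothing about its cause. Most miRNAs that set the median were on the factor in both groups (70 of the 100 tested), which limits the test. The size of the rise stays open, since quantile normalization kept 6 of 13 (miR-200b at 0.36), the mean of the references 6 and reference 3 only miR-21. Mesenchymal cells in the ACLT sort, which selected for OSCAR and CTR, stay open: miR-143 and miR-152 had a median of -0.717, but they are what is left of the list without its called members, each is about 1 SE from 0, and both were on the factor in both groups. Other splits are too few: 10 splits of the 6 samples cannot give a share under 0.05, 1 of them (the real one) called as many as 20 miRNAs, and the highest of the others called 0. An effect of ACLT on osteoclasts remains open as a hypothesis, and so does an origin of these values tied to the factor above, since whether a miRNA lay off the factor and whether it was higher went together.

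Assays 1 base apart may share signal. Assay cross-amplification within families stays open: of the 3 such pairs with a called member, 1 differed by over 1 on the log2 scale, miR-29a and miR-29c (2.25 and 0.90, with SE of 0.61 and 0.64), and miR-30a differed from miR-30d by 0.32 and from miR-30e by 0.37.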
